A study of Mus musculus with 2 samples.

How the data were processed

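The series measured single-cell RNA in CD45-positive leukocytes sorted from palate wounds of Col1a2CreERT.Il33f/f mice, in which tamoxifen removes Il33 from fibroblasts that express Col1a2. Each group is 1 library made from a pool of mice, the Il33 maintained group from 7 mice and 14 wounds and the Il33 deleted group from 8 mice and 16 wounds, collected at day 2. The authors sorted lymphoid and myeloid cells 1 to 1 per the labels. The ratio of the 2 sides was thus set by the sort, before any loss of cells to the UMI minimum, and shares were taken within each side. The maintained mice received corn oil and the deleted mice tamoxifen, so the drug and the deletion are confounded.

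The deposited values are raw UMI counts per gene and barcode, with all barcodes and 32285 genes in each library. The authors made these counts with Cell Ranger 6.1.2 against the mm10 genome per the submitters' processing notes. Gene positions came from an mm10 annotation matched on Ensembl identifiers.

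Barcodes with at least 500 UMIs, at least 250 genes and under 10% mitochondrial UMIs were kept as cells. Scrublet (scanpy 1.11.5) marked 1 of 7385 and 8 of 697 barcodes as doublets, a rate in the maintained library too low for the caller to have worked, and the marked barcodes were removed. Clusters were built over both libraries from 2000 variable genes, 30 principal components, 15 neighbours and Leiden at resolution 1 (leidenalg 0.10.2, igraph 0.11.9), without batch integration. The T cell and innate lymphoid clusters were clustered again alone. A cluster was named X-like from markers fixed before the data were examined, and it stayed unnamed with fewer than 3 detected markers or when its leading genes went against the name. A sub-cluster of the T cell and innate lymphoid cells that met no marker rule was instead called other T cell-like by default. It could then still be left unnamed by its leading genes. The other T cell-like sub-clusters had at least 13 of their markers detected against all other cells. The check on leading genes was settled after seeing the data, from 3 versions, and the other 2 are among the alternatives. It left 50 of 7384 cells (0.677%) and 12 of 689 cells (1.74%) in an unnamed cluster. Numerical work used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and scikit-learn 1.9.0, and plots used matplotlib 3.10.9.

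Because the libraries differed in depth, a second processing, called matched depth, was added after seeing the data. It thinned the deeper library at a probability of 0.111, kept barcodes of at least 100 UMIs in both libraries, and assigned each to the class whose cluster profile in the maintained library, over 1601 genes, had the highest multinomial likelihood. Genes enriched in empty barcodes were left out of the profiles. Unnamed clusters and clusters with more deleted than maintained cells gave no profile. These were c9 (20 maintained and 313 deleted cells), c18 (5 and 56) and the unnamed T sub-cluster (50 and 12). Barcodes of these kinds could only be assigned to other clusters. Genes used in the assignment were then compared on the thinned counts, and all other genes on all counts. The minimum, the margin of the assignment and the choice of genes were also made after seeing the data, and 8 versions were run. In maintained cells held out from the profiles and thinned, 90.9% of 2977 were assigned to their own class. The held-out cells had still been used to build the clusters that gave their class and to choose the genes. Cells of c9, c18 and the unnamed T sub-cluster were not among them. The rates given here can therefore overstate the accuracy for the barcodes assigned, above all in the deleted library. For Treg-like cells, 46 of 64 were recovered and 65.7% [53.4, 76.7] of those assigned were true. Of those assigned to the plasmacytoid dendritic-like, NK/ILC1-like and gamma-delta T-like classes, 52.9%, 68.5% and 76.2% were true.

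Counts were summed over the cells of a class in each library and expressed as CPM relative to the summed UMIs of that class. Ratios are log2 of deleted over maintained CPM, with an exact conditional Poisson 95% interval. Shares have exact Clopper-Pearson 95% intervals. A gene with 0 UMIs in 1 library was set at a floor of 3 counts there, and no ratio was given when that floor was not below the other library's level. List medians have an interval from 1000 Poisson redraws and a percentile among 10000 random lists matched on mean expression, given as a description of these libraries. Members of a list were called higher or lower at 1.5-fold, among members with at least 20 UMIs. All intervals cover counting error only, since each group has 1 library. No p-value, standard error or count of changed genes was made from cells.

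Named genes were chosen by a rule fixed at the same stage as the markers. It takes, per class and direction, the 8 genes with the largest ratio among those with at least 50 UMIs over both libraries, a CPM of at least 50 in 1 of them, and a CPM at least that of empty barcodes (under 100 UMIs). It leaves out mitochondrial, ribosomal protein, haemoglobin, antigen receptor, sex-linked and unnamed genes. It adds Il33, Il1rl1, Areg, Il10, Vegfa, Tgfb1, Il1b, Tnf and Arg1 in every class, and the 3 highest and 3 lowest members of the Treg lists.

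Alternatives fixed beforehand were minimums of 1000 and 300 UMIs, a mitochondrial limit of 5%, doublets kept, Leiden resolutions of 0.5 and 2, cells thinned to 500 UMIs, T cells called by a Foxp3 UMI, ratios centred on the median of all genes, equal weight per cell, empty-barcode RNA subtracted at 10% of the class total, and a minimum of 20 UMIs per gene. Alternatives added after seeing the data were matched depth and its versions at 50 and 200 UMIs, with margins of 2 and 4, with empty-barcode genes kept in the assignment and with all counts for every gene, the other naming checks, removal of the 6% of cells with the highest doublet scores, and, for the interferon list, empty-barcode RNA subtracted from the maintained library at the largest share that markers of the opposite side allow. Lists are described in classes with at least 100 cells in both libraries, a limit also set after seeing the data. The ratio and naming steps were tested on counts simulated for a class in both libraries, with 200 of 7768 genes changed 4-fold up or down. There, 96.5% of the intervals held the true ratio and all 16 named genes, the most the rule can name, were changed genes. The counts were Poisson draws, so the coverage of the Poisson intervals was set by the simulation. It had no background RNA or misassigned cells, and its UMI totals were near those of monocyte/macrophage-like cells at 500 UMIs. It does not cover smaller classes, such as Treg-like cells with 5309 deleted UMIs there.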

Results

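IL-33 is an alarmin, a nuclear cytokine released by stressed or damaged cells, and its receptor ST2 (Il1rl1) is carried by a subset of regulatory T cells (Tregs) among other leukocytes. The series asked how leukocytes of oral wounds differ when fibroblasts lack Il33, with Tregs and with pro-angiogenic and anti-inflammatory signals in view. CD45-positive cells from palate wounds at day 2 gave 1 library per group. The Il33 maintained library held 15756593 UMIs and the Il33 deleted library 2458264. There was no replicate in either group, so no difference below has a replicate check, and every interval in brackets is a 95% interval for counting error only.

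The libraries differed in UMIs per barcode. The maintained library had 7423 barcodes with at least 500 UMIs and the deleted library 698, although barcodes with at least 50 UMIs numbered 8223 and 9078. Their median was 1342 UMIs in the maintained library and 150 in the deleted library. After filtering, 7384 cells with a median of 1485.5 UMIs and 689 cells with a median of 623 UMIs remained. Shares and genes are therefore given at the planned minimum of 500 UMIs and at matched depth, where 6132 and 6847 barcodes had medians of 194 and 187 UMIs. Matched depth was chosen after seeing the data.

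**Figure D1:**
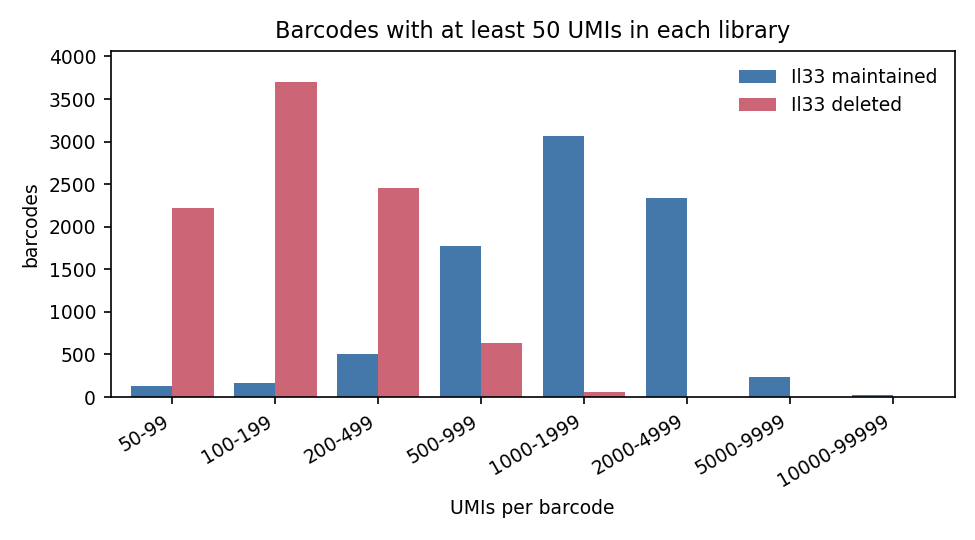
Number of barcodes (vertical axis) by UMIs per barcode (horizontal axis) in the Il33 maintained (blue) and Il33 deleted (red) libraries, for barcodes with at least 50 UMIs. Most deleted barcodes lie below 500 UMIs, with 3697 from 100 to below 200, while 3064 maintained barcodes lie from 1000 to below 2000.

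The targeted gene, Il33 (ENSMUSG00000024810, chromosome 19, 29925114 to 29960718, mm10), was near absent from both libraries. It had 6 UMIs over all barcodes of the maintained library and 3 over those of the deleted library, that is 0.381 CPM [0.140, 0.829] and 1.22 CPM [0.252, 3.57]. The sort for CD45 removes fibroblasts, the cells in which Il33 was deleted, so these counts do not check the deletion. Fibroblast markers summed to 18.1 CPM in maintained cells and 439 CPM in deleted cells, and Lrp1b, a gene abundant in empty barcodes, stood at 46.1 and 718 CPM. The deleted fibroblast marker UMIs numbered 214 in the 689 called cells and 221 in the 6847 barcodes of matched depth. They were thus not spread evenly over the barcodes of that library. Xist stood at 120 and 398 CPM and the Y-linked genes at 145 and 94.4 CPM in called cells, and at 143 and 121 CPM over all barcodes. Ribosomal protein genes, the transcripts of the translation machinery, had a log2 ratio of -1.27 over all cells.

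Treg-like cells, defined by Foxp3, Ctla4, Il2ra and Ikzf2 among other markers, took a larger share of T cells in the deleted library at 500 UMIs and a smaller share at matched depth. At 500 UMIs the share was 7.70% [6.53, 9.0] of 1870 maintained T cells and 30.4% [13.2, 52.9] of 23 deleted T cells, the latter being 7 cells. At matched depth it was 9.71% [8.30, 11.3] of 1596 and 6.44% [5.50, 7.49] of 2438, that is 155 and 157 barcodes. T cells with a Foxp3 UMI made up 2.67% (50 of 1870) and 4.35% (1 of 23), and 1.11% and 0 of 23 after thinning to 500 UMIs, where the exact upper bound of 0 of 23 is 14.8%. In maintained B cell-like cells, which should lack Foxp3, the shares were 0 of 1200 at a median of 1022 UMIs, against a median of 1413 in the T cells, and 0.0832% after thinning. The order of the libraries thus differed between the processings, which differ in the UMI minimum, the thinning and the way classes are assigned. Deleted minus maintained, the difference was 8.87 percentage points with the minimum alone lowered to 300 UMIs and 27.5 with cells thinned to 500 UMIs.

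Among the other classes, neutrophil-like cells were rare in the deleted library at 500 UMIs and took similar shares of both libraries at matched depth. The sort set the lymphoid to myeloid ratio of the sorted cells, but not that of the cells kept. At 500 UMIs the deleted library kept 28 lymphoid cells against 516 monocyte/macrophage-like cells alone. The maintained library kept 1479 other T cell-like and 2021 monocyte/macrophage-like cells. The depth gap can also set shares within each side. Of myeloid cells neutrophil-like cells were 30.2% [28.8, 31.6] and 1.86% [0.965, 3.23] at 500 UMIs, and 27.4% [25.9, 28.9] and 29.2% [27.7, 30.8] at matched depth. Monocyte/macrophage-like cells were 48.8% [47.3, 50.4] and 80.0% [76.7, 83.0] of myeloid cells at 500 UMIs, and 50.4% [48.7, 52.0] and 47.6% [45.9, 49.2] at matched depth. Cluster c9, led by Lrp1b and other genes of empty barcodes, held 313 of the 516 deleted monocyte/macrophage-like cells at 500 UMIs, and the like cluster c18 held 56 of the 113 deleted dendritic-like cells. Neither had a profile at matched depth, where such barcodes could only be assigned to other clusters. Dendritic-like cells were 16.6% and 17.5% at 500 UMIs and 17.6% and 17.1% at matched depth. Of lymphoid cells at 500 UMIs, other T cell-like cells were 46.5% [44.8, 48.3] and 28.6% [13.2, 48.7], and B cell-like cells 37.8% [36.1, 39.5] and 17.9% [6.06, 36.9], the deleted shares being 8 and 5 of 28 cells. Other T cell-like cells were 49.1% [47.1, 51.1] and 59.1% [57.4, 60.7] at matched depth, and B cell-like cells 31.2% [29.4, 33.1] and 23.5% [22.1, 25.0]. With a minimum of 200 UMIs in place of 100 the other T cell-like shares were 65.5% and 66.0%, a difference of 0.508 percentage points, and the B cell-like shares 9.79% and 11.8%. Monocyte/macrophage-like shares were 58.3% and 60.8% there. The difference of the other T cell-like shares and the order of the B cell-like and monocyte/macrophage-like shares therefore depended on the UMI minimum.

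**Figure D2:**
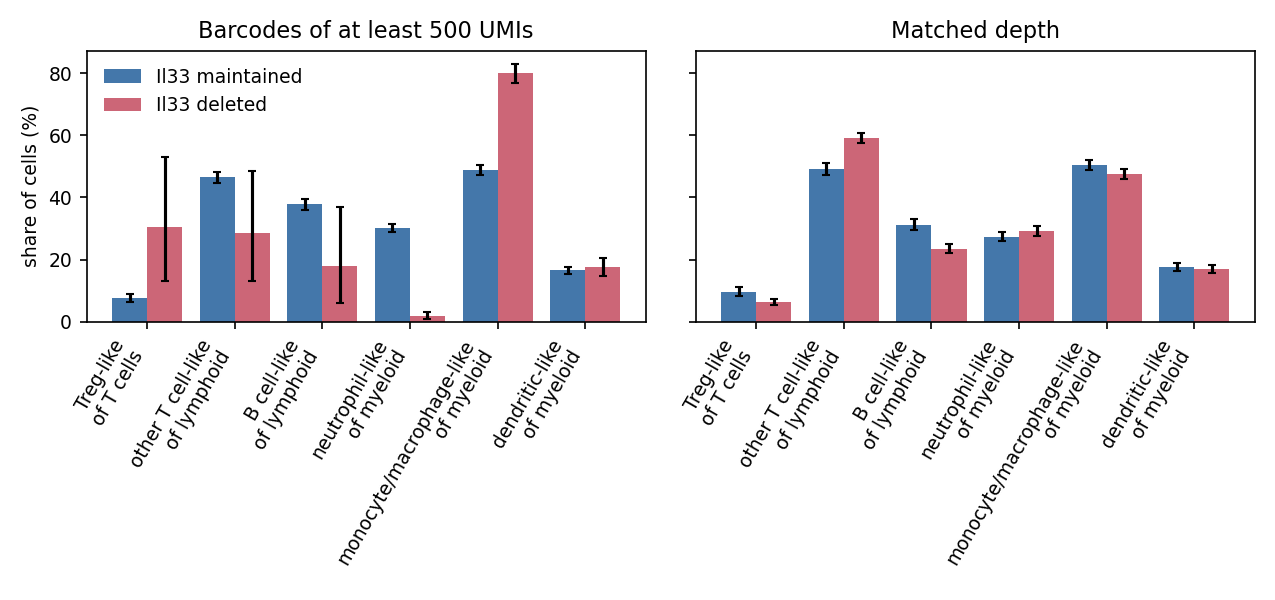
Share of each class (vertical axis, percent of T cells, lymphoid or myeloid cells as named on the horizontal axis) in the Il33 maintained (blue) and Il33 deleted (red) libraries, with exact 95% binomial intervals as bars. On the left, at 500 UMIs, neutrophil-like cells are 30.2% and 1.86% of myeloid cells, and on the right, at matched depth, they are 27.4% and 29.2%.

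Within Treg-like cells, the 7 deleted cells at 500 UMIs held 5309 UMIs, so 1 UMI was worth 188 CPM and most genes were not measurable. There Tuba1b and Stmn1, genes of the cytoskeleton of dividing cells, had log2 ratios of 3.02 [1.62, 4.18] and 2.46 [1.09, 3.58]. Srgn, a granule proteoglycan, had 933 and 1 UMIs, a log2 ratio of -4.19 [-9.50, -1.71], and Ifi27l2a, an interferon-induced gene, 808 and 2 UMIs, -2.99 [-6.04, -1.13].

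At matched depth, 155 and 157 Treg-like barcodes gave 314296 and 31972 UMIs. Il17a and Il17f, cytokines of type 17 lymphocytes, were the genes with the highest ratios in the deleted library, at 82.7 and 2502 CPM for Il17a (26 and 80 UMIs, log2 4.92 [4.26, 5.62]) and 66.8 and 1032 CPM for Il17f (log2 3.95 [3.12, 4.81]). The Il17a UMIs came from 2 of 155 and 7 of 157 barcodes, or 1.29% [0.157, 4.58] and 4.46% [1.81, 8.97], intervals that overlap. The interval of the Il17a ratio treats UMIs of the same barcode as independent, so it is too narrow. Il1rl1, the IL-33 receptor, had 68 and 2 UMIs (log2 -1.79 [-4.86, 0.12]) and Areg, a tissue-repair growth factor, 100 and 6 (log2 -0.76 [-2.24, 0.41]), both with intervals that include 0. Penk had 63 and 0 UMIs and was 2.14-fold lower with the 0 set at the floor of 3 counts, a value that is not a bound. Il10, an anti-inflammatory cytokine, was higher at 23 and 8 UMIs (log2 1.77 [0.40, 2.99]), as was Il18r1 at 1.45 [0.52, 2.30]. These intervals also treat UMIs of the same barcode as independent. Il10 was higher too in monocyte/macrophage-like cells at 500 UMIs and in neutrophil-like barcodes at matched depth. Since 65.7% of held-out assignments to the Treg-like class were true, its Il10 UMIs could come from other classes, which was not tested. Of the activation genes, Ctla4 was at 0.67 [0.21, 1.14], Tnfrsf4 at -1.03 [-1.64, -0.44] and Gzmb at -1.52 [-2.60, -0.62], while Foxp3 had 7 and 16 thinned UMIs (log2 1.32 [-0.04, 2.84]). The identity list had 15 measured members, 2 higher and 5 lower, with a median of -0.04 [-0.43, 0.30], and the ST2 list 18 members, 6 higher and 3 lower, with a median of 0.45 [-0.02, 0.66]. Members of both lists went both ways, and the intervals of both medians include 0. Il17f and Il17a also stand among the leading genes of the unnamed T sub-cluster, which had no profile at matched depth. Ctla4, Tnfrsf4, Gzmb and Foxp3 lead the cluster that defines the class, and none of the 16 genes named by rule at 500 UMIs was named at matched depth.

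Monocyte/macrophage-like cells were the class with the most UMIs in both libraries, and their interferon response genes were lower in the deleted library. At 500 UMIs (2021 and 516 cells), 23 of 31 measured interferon genes were lower and 1 higher by 1.5-fold, with a median log2 ratio of -1.36 [-1.51, -1.10], below all of 10000 random lists. Irf7, a transcription factor of the interferon response (chromosome 7, 141262706 to 141266481), stood at 288 and 37.6 CPM (log2 -2.94 [-3.82, -2.19]), Rsad2, an antiviral enzyme, at 291 and 42.9 CPM (log2 -2.76 [-3.57, -2.06]) and Ifit1 at 126 and 24.1 CPM (log2 -2.38 [-3.52, -1.45]). Cfb, a complement factor, Phf11b, Ly6a, Axl and Psmb10 completed the lowest genes, at log2 -2.96 to -2.37. Cfb, Rsad2 and Irf7 lead cluster c10, which held 295 and 3 cells, while cluster c9 held 20 and 313. Ifit2 and Oasl1 lead c10 as well. Without c10 at 500 UMIs, Irf7 was at -2.11 [-2.99, -1.35], Rsad2 at -1.17 [-1.99, -0.46] and Ifit1 at -0.76 [-1.99, 0.26], an interval that includes 0. The median of the interferon list without c10 was -0.53 [-0.78, -0.34], and at a minimum of 1000 UMIs, with all clusters, -0.75. At matched depth (1830 and 1671 barcodes, of which 321 and 75 in c10) the list median was -1.33 [-1.57, -1.07], with 24 of 31 members lower.

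In these cells the median of the pro-inflammatory cytokine and chemokine list was higher in the deleted library, and that of the hypoxia and glycolysis list lower. The list of pro-inflammatory cytokines and chemokines had a median of 0.60 [0.43, 0.64] at 500 UMIs, with 13 of 25 members higher and 2 lower, and 0.47 [0.27, 0.52] with 7 of 25 higher at matched depth. Tnf stood at 1063 and 1626 CPM (log2 0.61 [0.49, 0.73]) and Il10 at 331 and 671 CPM (log2 1.02 [0.82, 1.21]), while Il1b was at -0.15 [-0.23, -0.06]. The Treg identity and activation list was also higher in these cells, at 0.78 [0.55, 1.09] with 7 of 10 members higher and 0 lower, and at 0.74 [0.40, 0.85] with 5 of 7 higher at matched depth. The higher members at both settings included the TNF receptor Tnfrsf1b, the ectoenzymes Entpd1 and Nt5e, and Nrp1, while Ctla4, with 19 and 8 UMIs, and Icos, with 31 and 7, were measured at 500 UMIs alone. The pro-angiogenic list had a median of 0.19 [0.05, 0.34], 6 of 25 members higher and 2 lower, and the anti-inflammatory and resolution list 0.26 [0.14, 0.35], 8 of 28 higher and 4 lower, at percentiles 72.4 and 86.6 of random lists. Vegfa, the main endothelial growth factor, was at 0.31 [0.05, 0.57], Arg1 at 0.26 [0.13, 0.39], Tgfb1 at 0.16 [-0.12, 0.43] and Areg at -0.01 [-0.58, 0.51]. Plau, the urokinase protease, was among the highest genes at 1.82 [1.59, 2.05], with Nif3l1 at 3.44, Trp53cor1 at 3.09, Pccb at 2.85, Cpeb1 at 2.24, Fars2 at 2.00, Dennd5b at 1.87 and Hmga1b at 1.81. Hypoxia and glycolysis genes had a median of -0.46 [-0.59, -0.32], with 9 of 24 members lower and 0 higher. MHC class II presentation genes were at -0.35 [-0.64, 0.07], with 3 members higher and 4 lower, and at matched depth at -0.48 [-0.62, -0.11], with 3 of 14 higher and 5 lower. Cluster c9 held 313 of the 516 deleted cells behind these values at 500 UMIs, and at matched depth such barcodes could only be assigned to other clusters. The median ratio of all genes of the class was 0.13. Relative to it the pro-angiogenic list was at 0.06 and the anti-inflammatory list at 0.12, while the interferon list was at -1.49. Ribosomal protein genes of this class were at -0.88.

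Neutrophil-like cells numbered 1248 and 12 at 500 UMIs, where 1 UMI was worth 124 CPM in the deleted library. Lcn2, an iron-binding granule protein, had 4403 and 2 UMIs there (log2 -3.26 [-6.31, -1.41]), and Plcb1 93 and 7 (log2 4.11 [2.76, 5.21]). At matched depth, with 995 and 1027 barcodes, granule and immaturity genes were lower, with a median of -0.81 [-1.10, -0.35] and 5 of 8 members lower, and Retnlg at -1.48 [-1.73, -1.24]. Lcn2 and Retnlg are leading genes of clusters c4 (447 and 367 barcodes) and c8 (396 and 438). The remaining neutrophil-like cluster, c17, which neither gene leads, held 152 and 222. Interferon genes were lower at -0.62 [-0.84, -0.31], with Rsad2 at -2.22 [-3.01, -1.53]. The anti-inflammatory and resolution list was higher at 0.57 [0.32, 0.65], with 12 of 24 members higher and 0 lower, Il10 at 1.20 [0.79, 1.59] and Arg1 at 1.05 [0.62, 1.46]. Arg1 is also a leading gene of monocyte/macrophage-like cluster c5. The macrophage phagocytosis and lipid list was at 0.20 [0.06, 0.35] in these barcodes, or -0.0045 relative to the median of all genes. Whether macrophage barcodes or RNA in this class raised the anti-inflammatory list was not tested. The pro-inflammatory list was at -0.18 [-0.22, 0.05], Il1b at -0.05 [-0.14, 0.03], Tnf at 0.07 [-0.07, 0.21] and the pro-angiogenic list at 0.04 [-0.10, 0.26]. The median ratio of all genes was 0.20, and relative to it the anti-inflammatory list was at 0.37 and the granule list at -1.01.

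Other T cell-like cells numbered 1479 and 8 at 500 UMIs, where 1 UMI was worth 206 CPM. The genes named there by size rest on 1 to 3 deleted UMIs, such as Ccl5 (3586 and 2 UMIs, log2 -1.99 [-5.03, -0.13]) and Stx12 (52 and 3 UMIs, log2 4.70 [2.38, 6.33]). At matched depth, with 1219 and 1959 barcodes, type 1 and cytotoxic genes were lower, with a median of -0.52 [-1.04, -0.11] and 6 of 13 members lower. The size of this median depended on the setting, at -0.18 with a minimum of 200 UMIs and -0.97 at a margin of 4. Gzmb, a cytotoxic protease, stood at 98.4 and 11.8 CPM (log2 -3.06 [-4.95, -1.68]). Gzmb and Ifit3 lead cluster t7, which held 130 and 81 barcodes. Interferon genes were lower at -0.49 [-0.86, -0.26], with 11 of 26 members lower and 3 higher and with Ifit3 at -2.55 [-4.45, -1.17], and hypoxia and glycolysis genes at -0.56 [-0.68, -0.29], or -0.28 at a margin of 4. Among the highest genes were Ikbke at 2.84 [1.53, 4.52] and Cct6a at 2.54 [2.17, 2.94], both used in the assignment. Clusters t2 and t6 held 289 and 110 maintained and 759 and 345 deleted barcodes. The median ratio of all genes was 0.25, relative to which the type 1 and cytotoxic list was at -0.78. The 7 T cell receptor complex genes summed to 3950 and 2905 CPM, a log2 ratio of -0.44 [-0.57, -0.31].

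**Figure D3:**
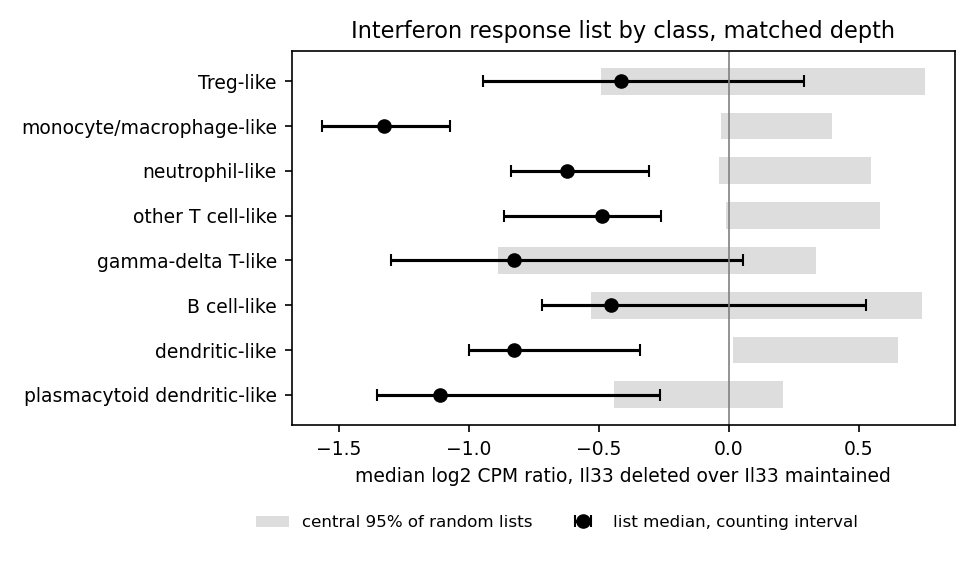
Median log2 CPM ratio (horizontal axis, Il33 deleted over Il33 maintained) of the interferon response list in each class (vertical axis) at matched depth, as points with bars for the counting interval, over the central 95% of random lists in grey. The points run from -1.33 in monocyte/macrophage-like cells to -0.42 in Treg-like cells, and the bars of the Treg-like, gamma-delta T-like and B cell-like classes include 0, and NK/ILC1-like cells, with 3 members measured, are not drawn.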

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

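Of the tests here, those on misassignment, on Foxp3, on free RNA at a bounded share and on the whole library were chosen after the results were seen, as was matched depth itself, on which all of them run.

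In the deleted library 8380 barcodes held at least 50 and under 500 UMIs, against 800 in the maintained library, a signal in barcodes that the planned minimum leaves out. Lrp1b stood at 14439 CPM among barcodes under 100 UMIs of the deleted library and at 2888 CPM in the maintained library, again in barcodes outside the planned comparison.

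The lower Treg-like share of T cells in the deleted library at matched depth has technical explanations that remain, and none was excluded. Barcodes of other classes assigned to the Treg-like class cannot be told apart from a real difference: at a margin of 4 the difference was -4.42 percentage points [-6.55, -2.44], but that margin left 46.5% of the maintained and 29.9% of the deleted Treg-like barcodes and so changes the difference itself, and held-out cells came from the maintained library alone. Misassignment at low depth, Treg-like cells lost to other classes included, cannot be told apart from it either, since the difference was -3.77 [-7.22, -0.42] at 200 UMIs and -3.52 [-5.42, -1.72] at a margin of 2, while Foxp3 CPM over all T cell-like barcodes had a ratio of 1.33 [0.726, 2.31] from 77 and 16 UMIs. The T cell receptor complex genes of the other T cells were at -0.44, which is consistent with barcodes of background RNA assigned to those cells and lowering the Treg-like share. Fewer Treg-like cells among all leukocytes could not be tested. The Foxp3 ratio over all assigned cells, 1.69 [0.953, 2.84], follows the lymphoid to myeloid ratio, which the sort and the UMI minimum set. Treg-like barcodes were 155 of 6132 (2.53%) and 157 of 6847 (2.29%) assigned barcodes, a ratio of 0.907 [0.722, 1.14]. Other T cell-like barcodes numbered 1219 and 1959, so the lower share of T cells came with more of these, not with a lower Treg-like count. Most of that increase lay in sub-clusters t2 (289 and 759 barcodes) and t6 (110 and 345). Sub-clusters t0, t1, t4 and t7 held 209, 365, 116 and 130 maintained and 267, 359, 148 and 81 deleted barcodes. The difference of the shares thus rests largely on t2 and t6. The loss of Il33, the tamoxifen and the pool of mice stay open and untested.

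The lower interferon response list at matched depth was tested against technical explanations. The interferon-high macrophage cluster alone does not account for it in monocyte/macrophage-like cells, since the median without that cluster was -0.68 [-0.91, -0.49], against -1.33 with it. The list was also below -0.3 in the 4 other classes tested, although the B cell-like interval includes 0. Cluster t7 of the other T cell-like class, led by Ifit3, was not set aside there. A general loss of transcripts of that abundance is argued against by a percentile of 0 among random lists in monocyte/macrophage-like cells, the class tested. Free RNA of the maintained library, planned as a subtraction of 10% (a median of -1.32) that decides nothing since the share is assumed, was bounded instead by markers of the opposite side at 2.66% to 8.69% of UMIs: subtraction of that share from the maintained library alone left -1.35 [-1.58, -1.10] in monocyte/macrophage-like cells and -0.47 or lower, with intervals below 0, in neutrophil-like, other T cell-like and dendritic-like cells, which argues against free RNA there, but gave 0.36 [-0.19, 1.13] in B cell-like cells, where free RNA could be the source. Background RNA in the barcodes of the deleted library was not bounded in any class, so dilution by it stays open. In other T cell-like cells the interferon median of -0.49 was near the -0.44 of the T cell receptor complex genes. In monocyte/macrophage-like, neutrophil-like, other T cell-like and dendritic-like cells, a lower interferon response stays open as a hypothesis. The deletion, the tamoxifen, a possible difference in the sex of the mice, the pool and the preparation of each library are not separated with 1 library per group.

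Ribosomal protein genes were lower and background genes such as Lrp1b higher in the deleted library. The highest ribosomal ratio among 7 classes at matched depth was -0.31 and the lowest -0.85, which is consistent with a property of the whole library such as RNA quality or capture. No biological explanation was tested.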

How the results depend on the processing

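Every value of matched depth and its versions, of the other naming checks and of the removal of high doublet scores came from settings chosen after seeing the data. Over shares, share differences, numbers of shared named genes and the main list medians, 353 of 475 values under an alternative stayed within the counting interval or within 1.5 times, 116 moved and 6 changed sign from a value whose interval excluded 0. Of those that stayed or moved, 12 also changed sign, from a value whose interval included 0. Over the dendritic-like shares and other lists, 698 of 778 stayed, 79 moved and 1 changed sign from an interval without 0, while 76 of those that stayed or moved changed sign from an interval that included 0. No paired analysis was possible because each group is 1 pool. The depth of the deleted library, 23 T cells at 500 UMIs, limits its T cell values, and other T cell-like genes gave no value at 1000 UMIs since no deleted cell was left. Unless said otherwise the cause was not tested.

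The Treg-like share difference, deleted minus maintained, was 22.7 percentage points at 500 UMIs and kept its sign at 300 UMIs (8.87), at 5% mitochondrial UMIs, with doublets kept, at both Leiden resolutions, after thinning, without the highest doublet scores and under both naming checks. It changed sign at matched depth (-3.27) and with T cells called by a thinned Foxp3 UMI (-1.11). In the 7 versions of matched depth it lay between -2.86 and -4.42. The interferon list in monocyte/macrophage-like cells lay between -0.75 and -1.62 over the alternatives at 500 UMIs and between -1.18 and -1.48 over those of matched depth.

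At matched depth, in place of 500 UMIs, the Treg-like shares were 9.71% maintained and 6.44% deleted. Other T cell-like shares were 49.1% and 59.1%, so their difference changed sign from -18.0 points, with an interval of [-33.4, 2.20], to 9.97, and the maintained B cell-like share was 31.2%. Neutrophil-like shares were 27.4% and 29.2%, so their difference changed sign to 1.85. The deleted monocyte/macrophage-like share was 47.6% and its difference changed sign to -2.81. Of the 16 genes named at 500 UMIs, matched depth also named 0 in Treg-like, 0 in other T cell-like and 1 in neutrophil-like cells.

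With T cells called by a Foxp3 UMI, the shares were 2.67% and 4.35% unthinned, a difference of 1.67, and 1.11% and 0% thinned. A Foxp3 UMI marked 50 and 1 unthinned T cells, fewer than the 144 and 7 cells of the Treg-like cluster.

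At 1000 UMIs 4 deleted lymphoid cells and 49 deleted myeloid cells were left. The deleted Treg-like share was 75.0% [19.4, 99.4], 3 of 4 T cells, and the difference 66.7. Other T cell-like shares were 50.8% and 0%, a difference of -50.8, and B cell-like shares 30.2% and 0%, where 0 of 4 has an upper bound of 60.2%. Neutrophil-like shares were 24.0% and 4.08% [0.498, 14.0], a difference of -19.9, and monocyte/macrophage-like shares 51.6% and 87.8% [75.2, 95.4], a difference of 36.1. The interferon list was at -0.75 and the pro-inflammatory list at 0.66 in monocyte/macrophage-like cells. Shared named genes were 7 in Treg-like, 2 in monocyte/macrophage-like and 1 in neutrophil-like cells.

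At 300 UMIs the maintained B cell-like share was 39.5%, the maintained monocyte/macrophage-like share 50.6% with a difference of 26.2, and the pro-inflammatory list 0.41. Shared named genes were 7 in Treg-like, 3 in neutrophil-like and 1 in other T cell-like cells. At 5% mitochondrial UMIs the maintained other T cell-like share was 44.3%, with 10 shared genes in Treg-like, 9 in monocyte/macrophage-like and 5 in other T cell-like cells. With doublets kept, 5 were shared in other T cell-like cells. Thinning to 500 UMIs gave maintained shares of 48.4% other T cell-like and 51.3% monocyte/macrophage-like.

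At Leiden resolution 0.5 the maintained neutrophil-like share was 34.5%, a difference of -32.2, and the maintained monocyte/macrophage-like share 41.8%, a difference of 36.7. At resolution 2 the latter share was 50.5%. With T sub-clusters checked among T side cells, maintained shares were 9.53% Treg-like, 39.7% other T cell-like and 42.6% B cell-like. With all T side markers the deleted other T cell-like share was 50%, and the difference changed sign to 2.63.

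At 500 UMIs, a minimum of 20 UMIs per gene left 8 shared named genes in Treg-like, 8 in neutrophil-like and 9 in other T cell-like cells. Subtraction of empty-barcode RNA left 9 in neutrophil-like and 10 in other T cell-like cells. Equal weight per cell left 10 and 9 in the same classes and gave an interferon list of -1.62. Centring put the anti-inflammatory list of monocyte/macrophage-like cells at 0.12.

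The following are versions of matched depth, all within its own classes. At 200 UMIs the other T cell-like shares were 65.5% and 66.0%, a difference of 0.508, and the B cell-like shares 9.79% and 11.8%, whose difference changed sign to 1.99. Neutrophil-like shares were 12.5% and 13.2%, and monocyte/macrophage-like shares 58.3% and 60.8%, whose difference changed sign to 2.47. The pro-inflammatory list of monocyte/macrophage-like cells was 0.55, and shared genes were 5 in Treg-like, 8 in neutrophil-like and 5 in other T cell-like cells.

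At 50 UMIs the other T cell-like shares were 45.5% and 54.0%, B cell-like 35.8% and 29.0%, neutrophil-like 32.3% and 35.4%, and monocyte/macrophage-like 46.8% and 42.1%. At a margin of 2 the Treg-like shares were 8.0% and 4.49%, B cell-like 35.9% and 26.2%, and the deleted neutrophil-like share 30.8%, with 3 shared genes in Treg-like and 10 in other T cell-like cells.

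At a margin of 4 the Treg-like shares were 7.84% and 3.42%, B cell-like 39.7% and 29.2%, a difference of -10.5, and neutrophil-like 31.0% and 33.0%. The maintained other T cell-like share was 44.5%, with a difference of 14.1, and the maintained monocyte/macrophage-like share 48.4%. The pro-inflammatory list of neutrophil-like cells changed sign from -0.18, with an interval that included 0, to 0.074, and shared genes were 2 in Treg-like and 8 in other T cell-like cells.

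Empty-barcode genes kept in the assignment left 9 shared genes in Treg-like cells, and so did the check with all T side markers. Equal weight per cell left 10 in Treg-like and 9 in neutrophil-like cells and put the pro-inflammatory list of neutrophil-like cells at -0.27. Centring put that list at -0.38, the pro-angiogenic list of monocyte/macrophage-like cells at 0.00041, and changed the sign of the phagocytosis and lipid list of neutrophil-like cells to -0.0045.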

Other observations

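The test on Il17a in this part, and every value at matched depth, was chosen after the result was seen.

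At matched depth the interferon list was also lower in dendritic-like cells, at -0.82 [-1.0, -0.34] with 18 of 30 members lower, and in plasmacytoid dendritic-like cells, at -1.11 [-1.35, -0.26] with 14 of 21, a class where 52.9% of held-out assignments were true. In NK/ILC1-like cells it was at 0.34 [-0.99, 1.05] over 3 members, so no difference was detectable there. The dissociation and early response list, which can follow the preparation, lay above the central 95% of random lists at matched depth in gamma-delta T-like cells, at 0.74 [0.34, 0.99] with 9 of 17 members higher and a percentile of 99.8. Its interval also lay above 0, at percentiles from 57.6 to 93.9, at 0.48 [0.05, 0.65] in plasmacytoid dendritic-like, 0.43 [0.21, 0.64] in other T cell-like (7 of 17 higher), 0.32 [0.15, 0.49] in dendritic-like, 0.28 [0.05, 0.48] in B cell-like, 0.25 [0.07, 0.44] in neutrophil-like and 0.19 [0.11, 0.26] in monocyte/macrophage-like cells (1 of 18 higher). Relative to the median of all genes the last 4 were at 0.06, 0.10, 0.05 and 0.04. In Treg-like cells it was at 0.30 [-0.26, 0.79] and in NK/ILC1-like cells at -0.42 [-1.04, 0.28]. Gamma-delta T-like cells had a type 2 list at 1.26 [0.40, 1.75] over 4 members. Cytotoxic genes were lower in NK/ILC1-like cells, at -1.09 [-1.27, -0.06] with 7 of 11 members lower, and 68.5% of held-out assignments to that class were true. In monocyte/macrophage-like cells at 500 UMIs the neutrophil ageing and activation list was at 0.43 [0.24, 0.55], macrophage phagocytosis and lipid genes at -0.17 [-0.33, -0.06] and the IL-33 receptor and signalling list at 0.46 [0.17, 0.64]. Oestrogen-responsive genes, a list for the tamoxifen given to 1 group, were at 0.21 [-0.50, 0.70] there and at 1.13 [0.48, 1.61] over 3 members in B cell-like cells at matched depth. Myc, a gene of this list, leads B cell-like cluster c13, which held 220 and 298 barcodes at matched depth, against 555 and 481 in c0. The mix of these clusters was not separated from the list's median. In monocyte/macrophage-like cells at 500 UMIs dissociation and early response genes were at 0.02 [-0.10, 0.14], type 17 genes at 0.05 [-0.42, 0.32] and cell cycle genes at 0.19 [-0.11, 0.52], the last at 0.30 [0.01, 0.49] at matched depth.

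The higher Il17a and Il17f of the deleted library's Treg-like barcodes at matched depth could come from gamma-delta T cells assigned to that class. The test could not decide, because gamma-delta T-like cells of this library at 2318 CPM of Il17a would have to give 108% of the class's UMIs to reach 2502 CPM, and the UMIs came from 7 barcodes. A first form of the test, which set 0 UMIs of 5 gamma-delta markers (at most 115 CPM) against the 1281 CPM that share would bring, was put aside after its value was seen, since no share above all of the class can occur.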
